A study of Mus musculus with 9 samples.

How the data were processed

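RNA sequencing was used to measure gene expression in 9 libraries of fluorescently sorted mouse tumour cells. Per the labels' protocols, total RNA was isolated with a micro-scale column kit, at least 100 ng entered each library, and cDNA was made with the SMART-seq v4 ultra low input kit, which copies polyadenylated RNA from few cells, followed by Nextera XT tagmentation. The genome build was mm9, per the submitters' processing notes. The aligner, the counting program, the gene annotation release and the read length were not given in the sources used here. The kit does not mark strand, so reads of overlapping genes on opposite strands, and reads shared between near-identical gene copies such as the haemoglobin, immunoglobulin and glutathione S-transferase families, cannot be assigned with certainty.

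The authors deposited 1 table of 23799 genes by Ensembl identifier and symbol, of which 166 were at 0 in all 9 libraries, and all 9 columns of values were used. The table carried the name CPM, but its columns summed to between 288171 and 992077 and differed between libraries. Multiplying each low value (under 20 reads) by the exonic length of its gene in GENCODE release M21 gave whole multiples of 1 step per library, within 0.02 of a whole number, for 62.5 to 74.2% of the values; the values alone did so for 3.2 to 4.6%. The values deposited by the authors were therefore read as RPKM, reads per kilobase of gene scaled by a read total per library. Lengths were found for 93.0% of the genes, from a later build than the authors', which is why no genome positions are printed. The step gave a scaling total of 12800000 to 131100000 reads per library, and the values with their lengths gave 21300000 to 128000000 reads on genes, so the scaling total was not the plain sum of gene reads. Because the values do not resolve to whole reads without gene lengths, the count-based tests planned for that case were not run.

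Libraries were grouped by the tumour model and site in their labels: BC primary tumour (numbers 1 and 5), BC lung metastasis (4 and 6), PDAC primary tumour (1 and 5), PDAC liver metastasis (1 and 5) and PDAC lung metastasis (1). The PDAC libraries of numbers 1 and 5 differ in age and genotype label and so came from separate animals. The labels do not say so of the BC libraries of a group, whose spread may be partly technical, and p-values measure the spread between these libraries. The submitters describe the metastases as matched, and PDAC libraries with the same number share an age and a genotype label, so the PDAC numbers were taken to pair samples by mouse. Across 12832 genes the deviations of PDAC primary 1 and PDAC liver metastasis 1 from their group means had a correlation of -0.165, so the values did not show this pairing. BC groups share no numbers and were not paired. No library pair held identical values.

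Each comparison was tested with limma 3.58.1 in R 4.3.3 (statmod 1.5.0) on log2(RPKM + 1), with a mean-variance trend and robust empirical Bayes moderation, for the 12832 genes with at least 1 RPKM in at least 2 of the 9 libraries. A fold change on this scale understates the change of genes with low values. All 9 libraries entered 1 fit with 1 mean per group (4 residual degrees of freedom, median prior 6.17), from which 6 contrasts were taken: BC lung metastasis against BC primary, PDAC liver and PDAC lung metastasis each against PDAC primary, the difference of the metastasis effect between the models, PDAC liver against PDAC lung metastasis, and PDAC against BC primary. Metastasis against primary over both models was fitted with the model as a covariate (6 residual degrees of freedom). Tests were two-sided with Benjamini-Hochberg adjustment over the genes tested, and a gene was called at an adjusted p under 0.05. The single PDAC lung metastasis library has no replicate and was assumed to vary like the other groups.

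Gene lists were tested with camera on the same fits, with a preset inter-gene correlation of 0.01 and adjustment over the lists of a comparison. Of 38 lists (770 genes, of which 754 were in the table, 7 of them matched by Ensembl identifier because their symbol had changed), 35 had at least 5 tested genes. Camera asks whether a list moves relative to the other genes, so directions of lists are given on that scale. Each list was also tested with a correlation estimated from the data and with fry, a rotation test of the list by itself. List members were also adjusted over the list alone. The lists, the tests, the alternatives and the rule for naming genes were fixed before the data were examined. The rule took, per direction, the 8 genes (4 for the last 3 contrasts) with the largest change among called genes whose libraries did not overlap and whose higher group averaged at least 5 RPKM, filled up by the smallest p where too few passed. It added 3 members of each called list and the genes Gstt1, Sirt6, Trp53, Lin28b and Igf2bp3 in every group, and passed over predicted loci. Some other genes that the rule named are not reported here.

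The steps were tested on simulated data built on the real libraries' values and spread, with 200 of 12832 genes raised by 1, 2, 4 or 8 on the log2 scale. At a change of 4, limma recovered 14% of raised genes in the BC lung comparison, 18% in PDAC liver, 8% in PDAC lung, 70% over both models, 0% for the difference between models, 2% for liver against lung and 10% for the primary tumours. At a change of 8 it recovered 72%, 84%, 48%, 94%, 20%, 48% and 78% in the same order, and in no comparison did it recover a raised gene at a change of 1. Between 0 and 3 unchanged genes were called per comparison. The simulated spread came from the fit with 1 mean per group. It leaves out differences between groups that the fit over both models holds in its residual, so the 70% and 94% may be too high. In the BC lung comparison, 5 of 5 raised lists were recovered with the preset correlation and 4 of 5 with an estimated one, without false calls. The simulated genes were drawn independently and the lists were random. False calls of the preset correlation for lists whose genes move together were therefore not tested by it.

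Alternatives were a pseudocount of 0.1 or 5, no filter on low values or a mean of at least 5 RPKM, TMM or quantile scaling, no trend and no robust step, library weights, only the libraries of a model, each library left out in turn, the replicate number as a block, equal weights of the models, and lung metastases alone, to which the list tests were added after the result was seen. Chosen after seeing the data were rescaling each library without the haemoglobin genes, leaving out the 3 libraries that list the fewest genes above 0 (BC lung metastasis 6, PDAC primary 5 and PDAC lung metastasis 1), and a crossed replicate block. The rescaling brought the summed RPKM of the genes other than haemoglobin to 1 common total. It therefore also removed differences in summed RPKM that haemoglobin did not make. Reads carry no molecular identifiers, so depth bounds counting error only, and library complexity is better read from the number of genes above 0.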

Results

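Gene expression was measured by RNA sequencing in 9 libraries of tumour cells that had been sorted by their fluorescent label from mice with primary tumours and metastases. The breast cancer (BC) libraries held GFP-positive cells of tumours grown from 4T1-eGFP, a labelled mouse mammary carcinoma line, at 28 days: 2 primary tumours (numbers 1 and 5) and 2 lung metastases (numbers 4 and 6). The pancreatic ductal adenocarcinoma (PDAC) libraries held YFP-positive cells of mice with a pancreatic Cre driver, a floxed p53 allele and a YFP reporter: 2 primary tumours (numbers 1 and 5), 2 liver metastases (numbers 1 and 5) and 1 lung metastasis (number 1). PDAC number 1 was taken at 25.67 weeks and its label adds floxed SIRT6 alleles. Number 5 was taken at 28.95 weeks without them. Age and SIRT6 label therefore cannot be separated from the number. The comparisons ask which genes differ between primary tumour and metastasis in each model, which differ in both, and whether the models differ.

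Genes of red blood cells and leukocytes were abundant in the PDAC metastases although the cells had been sorted. Haemoglobin genes made up 38.9% and 20% of the summed RPKM in PDAC liver metastases 1 and 5 and 38.6% in the PDAC lung metastasis, against 10.9% in PDAC primary 1, 0.0582% in PDAC primary 5 and 0.00607 to 0.107% in the BC libraries. S100a8 and S100a9, calcium-binding proteins of neutrophils, made up 14.0% in PDAC liver metastasis 5 and 0.00246% in PDAC primary 5. In PDAC primary 1 the immunoglobulin light chain gene Igkc had the highest value of any gene, 27940 RPKM, and in PDAC primary 5 the keratin gene Krt18 did, at 8157 RPKM. The estimated reads on genes ranged from 21300000 in the PDAC lung metastasis to 128000000 in BC primary 5, and the genes above 0 from 9530 to 20478 in the same libraries. BC lung metastasis 6 listed 10938 genes and PDAC primary 5 listed 10410. In PDAC primary 5 the mitochondrial enzyme gene Sdha was at 0.0247 RPKM, against 8.26 to 79.7 RPKM in the other libraries, and the general transcription factor gene Tbp was at 0.138 RPKM there and at 0.0584 RPKM in the PDAC lung metastasis. Genes that cells generally use were thus near 0 in these libraries, and a value of 0 is given below only as listed at 0. Across genes, the correlation of log2 values between the 2 libraries of a group was 0.953 for BC primary tumours, 0.818 for BC lung metastases, 0.749 for PDAC liver metastases and 0.552 for PDAC primary tumours. Genes are not independent replicates.

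**Figure D1:**
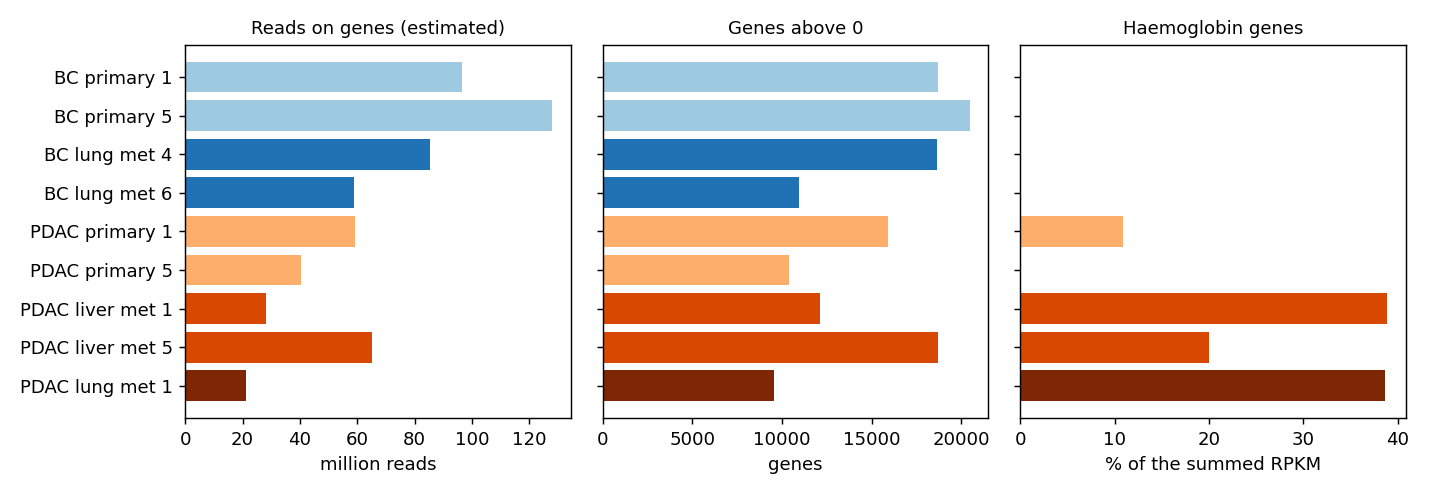
For each of the 9 libraries, bars give the estimated reads on genes, the number of genes above 0 and the percent of the summed RPKM taken by haemoglobin genes. The PDAC lung metastasis has the fewest reads (21300000) and genes (9530), and haemoglobin takes 20 to 38.9% in the 3 PDAC metastases and at most 0.107% in BC libraries.

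Genes named in advance were read in every library. Sirt6, a deacetylase gene, was at 6.23 and 5.81 RPKM in BC primaries 1 and 5 and at 4.96 and 0.208 RPKM in BC lung metastases 4 and 6. It was at 3.49 RPKM in PDAC primary 1 and 2.91 RPKM in PDAC liver metastasis 1, which carry the floxed SIRT6 label, and at 2.23 RPKM in PDAC liver metastasis 5, which does not. PDAC primary 5 and the PDAC lung metastasis listed it at 0. These values did not follow the labelled genotype, and a value per gene does not show whether single exons were lost. Gstt1 (ENSMUSG00000001663), a theta-class glutathione S-transferase, was at 0.89 and 4.25 RPKM in BC primaries and 10.9 and 19.8 RPKM in BC lung metastases. In PDAC it was at 3.17 RPKM and listed at 0 in the primaries, at 11.1 and 8.31 RPKM in the liver metastases and listed at 0 in the lung metastasis. Its log2 differences were 2.32 ± 1.15 (SE, n = 2 against 2; limma adjusted p = 0.974) in BC and 2.38 ± 1.15 (adjusted p = 0.816) for PDAC liver. Over both models the difference was 1.73 ± 0.93 (n = 5 against 4; adjusted p = 0.853), and none passed. Trp53, the gene of p53, ranged from 0.639 to 17.5 RPKM, without a passing difference in any comparison. The oncofetal RNA-binding protein genes Lin28b and Igf2bp3 did not pass the filter and were not tested. Lin28b was at 0.00132 and 0.000842 RPKM in BC primaries 1 and 5 and listed at 0 in the other libraries. Igf2bp3 was at 0.00275 and 0.0176 RPKM in BC primaries 1 and 5 and at 0.00493 RPKM in BC lung metastasis 6. It was listed at 0 in the others. No measured gene matched Ptf1a.

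Lung metastases of the BC model were compared with its primary tumours, gene by gene with the spread pooled over all 9 libraries, and then by list. S100a8 was at 15.0 and 13.2 RPKM in the primaries and at 1500 and 939 RPKM in the metastases, a log2 difference of 6.30 ± 1.69 (SE, n = 2 against 2). Saa3, an acute-phase protein gene, was at 9.10 and 8.33 RPKM against 102 and 57.8 RPKM (3.00 ± 0.59). Ifitm3, an interferon-induced membrane protein gene, was at 1450 and 1090 RPKM against 3390 and 6020 RPKM (1.84 ± 0.49). Lower values in metastases were found for Dmp1, a matrix phosphoprotein gene (32.2 and 51.5 against 8.47 and 0.0465 RPKM, -3.73 ± 1.12), and Apln, which encodes the peptide apelin (7.09 and 10.0 against 2.04 RPKM and listed at 0, -2.44 ± 0.74). None passed: limma called 0 of 12832 genes, with 265 at an unadjusted p under 0.05 (113 higher, 152 lower) and a smallest adjusted p of 0.974. The counts at an unadjusted p under 0.05 were 55 higher and 401 lower when rescaled without haemoglobin, and 138 and 153 with quantile scaling. The rescaling also gives all libraries a common sum, and haemoglobin took at most 0.107% of the summed RPKM in BC libraries. The other genes named by the rule were Cytl1, Lrg1, Stra6 and Ly6a with higher values (log2 2.44 to 3.89), Scgb1a1, listed at 0 in the primaries, and Adamts8, Ube2ql1, Wisp1, Ephb6, Fam171a1 and Gpr153 with lower values (-2.83 to -2.18). When only the 4 BC libraries were fitted, with 2 residual degrees of freedom, limma called 73 of 10384 genes (34 higher, 39 lower). Among them were S100a8 (adjusted p = 1.71e-18, 1.71e-18 to 1.000 over its 20 alternatives), S100a9, Lrg1, Ly6a, Saa3 and H2-Ab1. With 2 residual degrees of freedom, so small a p rests largely on the spread taken from the other genes. Some genes called lower, such as Dmp1 and Glud1 (31.8 and 35.8 against 15.6 RPKM and listed at 0), were near 0 only in metastasis 6, which lists 10938 genes. Others, such as Fbln2 (95.7 and 66.3 against 6.16 and 4.15 RPKM), were low in both metastases.

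By camera at a preset correlation, 11 of 35 lists moved relative to the other genes in BC, whose median log2 difference was -0.29. Of 17 neutrophil genes 17 had positive differences (median 1.73; camera adjusted p = 3.36e-08). Of 9 genes of MHC class II presentation, which display antigen to helper T cells, 9 did (median 2.88; adjusted p = 2.11e-07), with H2-Ab1 at 58.0 and 114 against 777 and 857 RPKM. Oxidative phosphorylation genes (24 of 30 positive, median 0.99, adjusted p = 3.61e-10) and cytosolic ribosomal protein genes (33 of 35 positive, median 0.63, adjusted p = 2.8e-09) were also higher. Cox7a2, a cytochrome oxidase subunit gene, was at 194 and 163 against 413 and 1115 RPKM. The 65 genes of these 2 lists gained 0.23 over the other genes in metastasis 4 and 1.81 in metastasis 6. Their median of 0.7 lay at percentile 63.88 of random lists matched on gene length and expression, whose median was 0.68. Lung epithelial genes were higher (9 of 9 positive, adjusted p = 3.05e-05), with the club cell gene Scgb1a1 listed at 0 in both primaries and at 6.05 and 24.3 RPKM in the metastases. The erythroid and platelet list (0.0178), MHC class I presentation (0.0199) and glutathione synthesis and peroxide removal (0.0459) were higher by camera adjusted p. Immediate early genes (0.0277), hypoxia targets (0.0331) and basement membrane, integrins and laminins (0.0459) were lower. No member passed over all genes, and adjusted over the list alone 1 did, Scgb1a1. With an estimated correlation camera called 0 of the 11 lists (adjusted p = 0.782 to 0.813), and fry called 0. Without lung metastasis 4 the lists of neutrophil (mean gain over the other genes 1.84), MHC class I (0.68), erythroid (2.33), glutathione synthesis (0.63) and basement membrane genes (-0.65) were no longer called. Without lung metastasis 6 the same held for ribosomal (0.08), erythroid (0.74), glutathione synthesis (0.11), hypoxia (-0.17) and immediate early genes (-0.24). The ribosomal (0.08), glutathione synthesis (0.11), hypoxia (-0.14) and immediate early calls (-0.24) were also lost without the 3 libraries with the fewest genes, of which it is 1. Without primary 1 the hypoxia (-0.67) and immediate early (-0.41) calls were lost, and without primary 5 those of basement membrane (-0.32) and glutathione synthesis (0.08). The basement membrane call was lost without PDAC liver metastasis 5 (-0.77), and the glutathione synthesis call without PDAC primary 1 or 5 (0.36 and 0.37).

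Liver metastases of the PDAC model had higher values of genes that hepatocytes secrete than their primary tumours. Apoa2, an apolipoprotein of high-density lipoprotein, rose from 0.0791 and 0.0594 RPKM in the primaries to 424 and 517 RPKM in the liver metastases (log2 8.78 ± 0.97, SE, n = 2 against 2; limma adjusted p = 0.0425). It was at 0.875 RPKM in the PDAC lung metastasis. The fibrinogen chain gene Fgb was at 0.0129 and 0.0194 against 88.7 and 335 RPKM (7.42 ± 0.98). Apoc3, Vtn, Azgp1, Apoa5 and Fetub were listed at 0 in both primaries and at 23.8 to 142 RPKM in the metastases. These genes and Ahsg (6.69 ± 0.91) did not pass, at a limma adjusted p of 0.0563. Lower values were found for the trypsinogen gene Prss2 (13.6 and 95 RPKM against listed at 0 and 0.506 RPKM, -4.93 ± 1.00; adjusted p = 0.167) and Ly6d (2260 and 980 against 238 and 127 RPKM, -3.09 ± 0.81; adjusted p = 0.341). Neither these nor Tmem163, Cyp21a1, Samd5, Bmyc, Wdr55 and Kif12 (-4.22 to -2.70) passed. Apoa2 was the only gene called of 12832, with 821 at an unadjusted p under 0.05 (628 higher, 193 lower; 418 and 328 when rescaled without haemoglobin, 567 and 259 with quantile scaling). It was not called with the replicate number as a block (limma adjusted p = 0.115, 0.00374 to 0.404 over its 20 alternatives), and the block called 0 genes. Leaving out PDAC primary 1 gave 1032 genes (766 higher, 266 lower). Without PDAC primary 5, either liver metastasis or any 1 BC library, 0 were.

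Of 35 lists, 17 moved in the PDAC liver comparison. Of 21 hepatocyte genes 19 had positive differences, 1 passed over all genes and 16 adjusted over the list alone (median 4.99; camera adjusted p = 1.38e-27, adjusted p = 0.153 with an estimated correlation, fry adjusted p = 0.0074). Macrophage genes (24 of 24 positive, 5 over the list alone, adjusted p = 2.46e-13), erythroid and platelet genes (10 of 10 positive, 10 over the list alone, 5.03e-12) and neutrophil genes (16 of 17 positive, 9 over the list alone, 4.23e-11) were higher by camera. Tyrobp, a myeloid signalling adaptor gene, was at 474 and 139 against 1830 and 4330 RPKM. The platelet factor gene Pf4 was at 47.0 and 0.0545 against 442 and 377 RPKM, and S100a9 at 323 and 2.39 against 2560 and 38000 RPKM. Proliferation genes were higher (28 of 30 positive, median 2.11, adjusted p = 7e-09), for example the mitotic activator gene Cdc20 at 12.0 and 0.0342 against 60.4 and 59.6 RPKM. Primaries 1 and 5 listed 27 and 15 of the 30 genes above 0, so low values in primary 5 are limited by its few detected genes. Lists of endothelial (0.000895), pan-leukocyte (0.0011), immediate early (0.00175), NF-kB target (0.00558), lymphocyte (0.015), NRF2 target (0.019), fibroblast (0.0432) and glutathione synthesis genes (0.0432) were also higher by camera adjusted p. Epithelial genes (18 of 18 negative, adjusted p = 3.24e-06) and pancreatic ductal genes (15 of 15 negative, 1.33e-05) were lower, as were basement membrane (0.00897) and ribosomal protein genes (0.0412). The adhesion molecule gene Epcam was at 52.9 and 1150 against 25.1 and 20.1 RPKM. Camera with an estimated correlation called 0 of the 17 lists (adjusted p = 0.6 to 0.846 for those other than hepatocyte genes). Adjusted over the list alone, 2 immediate early genes and 1 gene of glutathione synthesis, Gpx1, also passed. The primaries differed in these groups. The median log2 difference of the liver metastases over the epithelial list was 0.47 from primary 1 and -4.39 from primary 5, over the ductal list 0.45 and -4.06, and over the lymphocyte list -1.39 and 4.57. It was 1.24 and 2.95 over the proliferation list, 1.66 and 3.3 for macrophage, 3.24 and 6.27 for neutrophil and 2.55 and 8.94 for erythroid genes, and 4.99 from each for hepatocyte genes. Without primary 5 the epithelial (0.58), lymphocyte (-1.18), pan-leukocyte (-0.01) and basement membrane lists (0.19) turned their sign, and the ductal (-0.02) and ribosomal (-0.06) calls were lost. Without the 3 libraries with the fewest genes, an alternative chosen after seeing the data, the epithelial (0.59), lymphocyte (-1.17) and basement membrane lists (0.19) also turned their sign, and the ribosomal (-0.06), pan-leukocyte (-0.01) and ductal (-0.23) calls were lost. Without primary 1, NF-kB (1.53), NRF2 (0.72), endothelial (1.24), fibroblast (0.83), glutathione synthesis (0.41) and immediate early genes (0.47) were lost. Without liver metastasis 1, NF-kB (0.78), endothelial (0.36), fibroblast (0.56) and glutathione synthesis genes (0.26) were lost, the last also without BC lung metastasis 4 or 6 (0.58 each). Without liver metastasis 5, NRF2 (0.48), basement membrane (-0.37), immediate early (0.33), lymphocyte (1.32), pan-leukocyte (0.96) and ductal genes (-1.19) were lost and ribosomal protein genes reversed (0.26). The replicate block ended the ribosomal call (camera adjusted p = 0.0506, 2.08e-08 to 0.846 over its alternatives) and the fibroblast call (0.0518, 0.014 to 0.714).

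**Figure D2:**
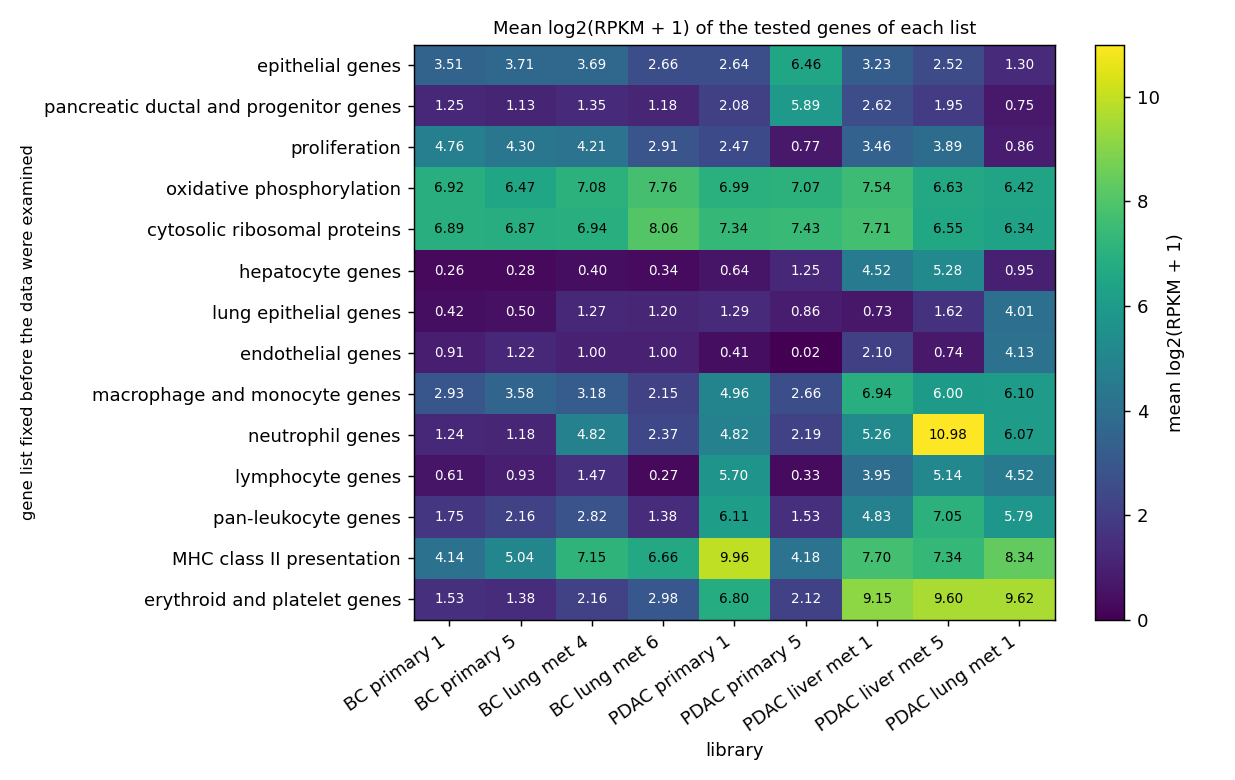
Each cell gives the mean log2(RPKM + 1) of a gene list (vertical) in a library (horizontal), for 14 lists. The hepatocyte list is at 4.52 and 5.28 in the PDAC liver metastases and between 0.26 and 1.25 in the other 7 libraries, and the endothelial list is at 4.13 in the PDAC lung metastasis.

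The single PDAC lung metastasis was compared with the PDAC primary tumours for genes of lung tissue, blood vessels and tumour epithelium. Sftpc, the surfactant protein of alveolar type 2 cells, rose from 0.978 and 0.278 RPKM in the primaries to 34200 RPKM (log2 14.39 ± 1.57, SE, n = 1 against 2; limma adjusted p = 0.025). Cldn5, a tight junction protein gene of endothelium, was listed at 0 in both primaries and at 302 RPKM (adjusted p = 0.0335), and Tmem100 and Scgb1a1 were listed at 0 against 413 and 90.8 RPKM. Hpgd, an enzyme that inactivates prostaglandins, rose to 588 RPKM (9.18 ± 1.36) and the fatty acid transporter gene Cd36 to 111 RPKM (6.78 ± 1.07). Lims2 (6.19) and Ch25h, listed at 0 in both primaries, rose as well. Cyc1, a subunit gene of respiratory complex III, fell from 265 and 110 RPKM to 0.131 RPKM (-7.25 ± 0.92; adjusted p = 0.0348). Ndufa10 of complex I (-6.83), Basp1 (-7.11), Krtcap3 (-6.95), Uchl5 (-6.73) and the tubulin gene Tubb6 (-6.63) fell too, and Nudt14 and Polr2d were called with the lung metastasis listed at 0. limma called 75 of 12832 genes, 22 higher and 53 lower, with 1765 at an unadjusted p under 0.05 (742 higher, 1023 lower; 640 and 1036 when rescaled without haemoglobin, 1061 and 719 with quantile scaling). The lung metastasis listed 611 of 3229 genes with a mean above 20 RPKM in the other libraries (18.92%) at under 0.5 RPKM, among them 47 of the 53 called lower. Quantile scaling called 161 genes (121 higher, 40 lower), the replicate block 0 and the PDAC libraries alone 1. Leaving out PDAC primary 1 gave 1547 genes and leaving out PDAC primary 5 gave 170. Leaving out BC lung metastasis 6 gave 1, and leaving out any other BC library gave 0.

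Lists moved in the PDAC lung comparison, 12 of 35, for blood vessel, blood cell and epithelial genes. Of 13 endothelial genes 13 had positive differences, 1 passed over all genes and 10 adjusted over the list alone (median 4.07; camera adjusted p = 4.45e-14), for example Egfl7, a secreted vessel protein gene, at 0.925 and 0.00891 against 273 RPKM. Erythroid and platelet genes (10 of 10 positive, 9 over the list alone, 1.87e-09), macrophage genes (22 of 24 positive, 4 over the list alone, 1.49e-08), neutrophil genes (12 of 17 positive, 3 over the list alone, 0.000166) were higher by camera. So were lung epithelial genes (7 of 9 positive, 2 over all genes and 3 over the list alone, 0.000529). Immediate early (0.000166; 3 higher and 1 lower over the list alone), pan-leukocyte (0.00214), lymphocyte (0.00404) and NF-kB target genes (0.0213) were higher too, the last with a median of -0.03 and a mean of 0.91. Epithelial genes (17 of 18 negative) and ductal genes (15 of 15 negative) were lower at an adjusted p of 4.88e-05 each, with 2 members each over the list alone, and ribosomal protein genes at 0.00404. Krt19, a keratin of ductal epithelium, was at 214 and 2180 against 0.338 RPKM and did not pass (limma adjusted p = 0.0507). Camera with an estimated correlation called 0 of the 12 lists (adjusted p = 0.751 to 0.929), and fry called 0. Without PDAC primary 5 the epithelial (-0.96), ductal (-2.09), pan-leukocyte (0.44) and ribosomal (-0.25) calls were lost and the lymphocyte list turned its sign (-0.54). The replicate block ended the NF-kB and lymphocyte calls (camera adjusted p = 0.0765 each, 1.88e-08 to 0.926 over the alternatives for lymphocyte genes and 0.0126 to 0.751 for NF-kB targets).

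Over both models, metastases were compared with primary tumours for a difference that the models share, with the model as a covariate. S100a8 had higher values in 5 of 5 metastases than in the primaries of the same model (log2 7.06 ± 1.06, SE, n = 5 against 4; limma adjusted p = 0.051), as did Ifitm3 (2.17 ± 0.32, adjusted p = 0.051) and the neutrophil genes S100a9 (6.99 ± 1.13) and Retnlg (7.01 ± 1.14; adjusted p = 0.079 each). Gpx1, a peroxide-removing enzyme gene, was at 1100 to 1750 RPKM in the primaries and 1800 to 9860 RPKM in the metastases (1.69 ± 0.33). It did not pass, nor did Lrg1, Stfa2l1 and Hp (limma adjusted p = 0.215 to 0.347). Mmp14, a membrane-bound matrix protease gene, was at 211, 215, 8.93 and 172 RPKM in the primaries and at 112, 19.6, 4.70, 2.98 and 0.0904 RPKM in the metastases. It, Calu, F2rl1, Palmd, Loxl4, Kcnk5, Thumpd1 and Prss2 had lower values (-3.23 to -2.27) without passing (limma adjusted p = 0.853). limma called 1 of 12832 genes, Gm11428. Its symbol has the form that the rule passed over, so it lay outside the rule and was chosen after its values were seen. It rose from 36.3 and 16.3 to 457 and 370 RPKM in BC and from 365 and 35.8 to 3418, 4581 and 3646 RPKM in PDAC (4.58 ± 0.58; adjusted p = 0.0371). At an unadjusted p under 0.05 there were 628 genes (281 higher, 347 lower; 159 and 780 when rescaled without haemoglobin, 361 and 245 with quantile scaling), and 474 genes separated the same way in both models, against 427.7 expected by chance. Leaving out PDAC primary 1 gave 10 genes and leaving out PDAC primary 5 gave 3, all higher and Gm11428 among them. Leaving out PDAC liver metastasis 1 gave 1 other gene, leaving out BC primary 1 gave Gm11428, and leaving out each of the other 5 libraries gave 0. With mouse as a random replicate block 6 genes were called, all higher.

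Of 35 lists, 16 moved over both models. Neutrophil genes (16 of 17 positive, 8 adjusted over the list alone, median 2.98, camera adjusted p = 7.13e-17), erythroid and platelet genes (10 of 10 positive, 10 over the list alone, 1.71e-14) were higher. So were macrophage genes (22 of 24 positive, 2 over the list alone, 3.51e-09) and hepatocyte genes (19 of 21 positive, 1 over the list alone, 4.68e-09). In BC alone, 17 of 24 macrophage genes (median -0.62) and 8 of 13 endothelial genes (median -0.09) had negative differences. The mean hepatocyte gain over the primaries was 4.22 and 5.22 in the PDAC liver libraries and 0.01 to 0.17 in the 3 lung libraries. Endothelial (1.35e-06), pan-leukocyte (3.6e-05), MHC class II (4.83e-05), lymphocyte (0.000644), glutathione synthesis (0.00115; Gpx1 over the list alone), lung epithelial (0.00247), oxidative phosphorylation (0.00257), MHC class I (0.00257) and NF-kB target genes (0.0261; 2 over the list alone) were higher by camera adjusted p. Epithelial genes (18 of 18 negative, 4.83e-05), basement membrane genes (15 of 16 negative, 0.000753) and ductal genes (15 of 15 negative, 0.000753) were lower, for example the laminin chain gene Lamb3 (-2.83 ± 0.99). Glutathione S-transferases did not move (10 of 21 positive, camera adjusted p = 0.696). Nor did proliferation (0.14), hypoxia (0.288), glycolysis (0.842), mesenchymal transition (0.842), p53 target (0.842), Wnt target (0.303), TGF-beta target (0.902), matrix protease (0.693) or type I interferon genes (0.0582). No list was called with an estimated correlation (adjusted p = 0.361 to 0.694 for the 16), and fry called 0. Without PDAC primary 5 the epithelial (0.01), lymphocyte (-0.14) and ductal (-0.02) lists lost their call, the first 2 with the sign turned. The same held for the pan-leukocyte (0.34), basement membrane (-0.33), MHC class I (0.37) and NF-kB (0.32) calls. Without the 3 libraries with the fewest genes the epithelial (0.42), lymphocyte (-0.19) and ductal (0.06) lists turned their sign, and the MHC class II (0.14), lung epithelial (0.46), MHC class I (0.29) and basement membrane (-0.36) calls were lost. The NF-kB call was also lost without PDAC primary 1 (0.58), PDAC liver metastasis 1 (0.44) or the PDAC lung metastasis (0.53), and the oxidative phosphorylation call without BC primary 5 (0.16) or BC lung metastasis 6 (0.02).

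**Figure D3:**
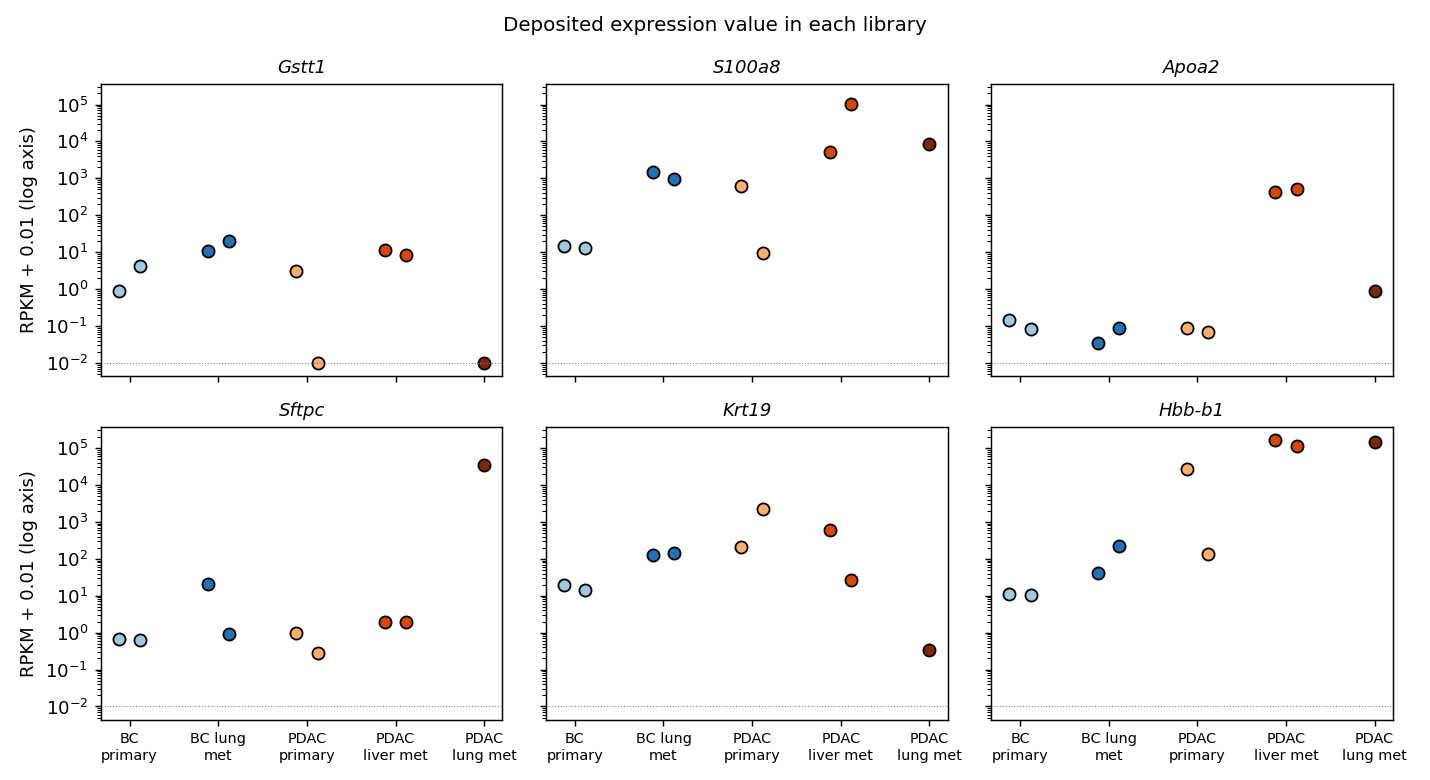
Each point is 1 library, with RPKM + 0.01 on a log axis, for Gstt1, S100a8, Apoa2, Sftpc, Krt19 and Hbb-b1 in the 5 groups. S100a8 lies at 939 to 101000 RPKM in the 5 metastases and at 9.28 to 609 RPKM in the 4 primary tumours, Apoa2 at 424 and 517 RPKM in the PDAC liver metastases and Sftpc at 34200 RPKM in the PDAC lung metastasis.

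The metastasis effect was tested for a difference between the models, taken as BC minus PDAC. Eci1, an enzyme of fatty acid oxidation (5.23 ± 1.00, SE, n = 9 libraries), Bin1 (5.46 ± 1.06), Polr2d (5.32 ± 1.05) and Igtp, an interferon-induced GTPase gene (5.43 ± 1.16), had higher effects in BC. Ch25h (-4.30), Nfkbiz (-5.11), the stress gene Gadd45a (-4.03) and the endothelial adhesion gene Esam (-5.55) had higher effects in PDAC. None passed: limma called 0 of 12832 genes, with 818 at an unadjusted p under 0.05 (347 higher, 471 lower) and a smallest adjusted p of 0.734. Leaving out PDAC primary 1 gave 104 genes (39 higher, 65 lower). Camera called 11 lists, with ductal, epithelial, ribosomal and oxidative phosphorylation genes higher in BC and 7 lists lower, and with an estimated correlation 0 (smallest adjusted p = 0.679). It called 22 without the 3 libraries with the fewest genes, but not the ductal (0.58), ribosomal (0.14) or oxidative phosphorylation lists (0.15), nor the epithelial list, which turned its sign (-0.32). With lung metastases only it called 9 of the 11, without hepatocyte (0.09) and proliferation genes (-0.24). Without PDAC primary 5 the epithelial (0.16), ductal (1.54) and proliferation (-0.87) calls were lost. The hepatocyte call was lost without PDAC primary 1 (-1.22) or PDAC liver metastasis 1 (-1.41) or 5 (-0.94), and the NF-kB call without BC lung metastasis 4 (-1.55) or PDAC liver metastasis 1 (-1.19).

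PDAC metastases of the liver were compared with the single lung metastasis, which was assumed to vary like the other groups. Cyc1 was higher in the liver metastases (327 and 117 against 0.131 RPKM, log2 7.44 ± 0.92, SE, n = 2 against 1). Sftpc (1.94 and 1.95 against 34200 RPKM, -13.50 ± 1.57), Tmem100 (-8.67 ± 0.98) and Cldn5 (-8.21 ± 1.00) were lower. The limma adjusted p was 0.0295 for each of these 4 genes. Acaa2, an enzyme of fatty acid oxidation (165 and 62.1 against 0.103 RPKM), Apoa2 (7.97 ± 1.19), Basp1 and Tinag did not pass (adjusted p = 0.0527). limma called 4 of 12832 genes, with 1366 at an unadjusted p under 0.05, and 0 with the replicate block. Hepatocyte genes (15 adjusted over the list alone, camera adjusted p = 2.04e-14, fry adjusted p = 0.0137), proliferation genes (5 over the list alone, 1.38e-05) and glycolysis genes (17 of 20 positive, 0.0251) were higher in liver. Rrm2, a subunit gene of ribonucleotide reductase, was at 30.6 and 70.1 against 0.0282 RPKM. The lung library listed fewer genes: 16 of 30 proliferation genes were above 0 there, against 28 and 30 in liver metastases 1 and 5. Of genes with a mean above 20 RPKM in the other libraries, 18.92% were under 0.5 RPKM in it. That share was 4.75% and 0.94% in the liver metastases, and lower values in lung are limited by this. Endothelial (2 over the list alone, 1.59e-11) and lung epithelial genes (3 over the list alone, 2.58e-05) were higher in lung. With an estimated correlation camera called 0 of these (adjusted p = 0.448 to 0.959). Leaving out PDAC primary 1 or 5 gave 329 and 328 genes, and leaving out any 1 BC or liver library gave 0. The glycolysis call was lost with the replicate block (camera adjusted p = 0.0961, 0.0153 to 0.959 over its alternatives) and without PDAC primary 1 (0.89) or 5 (0.88) or liver metastasis 1 (0.72) or 5 (0.81).

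Primary tumours of the models were compared as a reference, since mouse, tissue of origin, age and fluorophore differ with the model. Ly6d, a surface antigen gene, was higher in PDAC (0.328 and 0.386 RPKM in BC against 2260 and 980 RPKM, log2 10.10 ± 0.81, SE, n = 2 against 2; limma adjusted p = 0.00204), as were Chi3l3, a chitinase-like protein gene of macrophages (9.83 ± 0.98, 0.00846), Saa3 (5.42 ± 0.59, 0.0117) and Plac8 (7.19 ± 0.82, 0.0155). Oaf, Sdc2, Tpm3-rs7 and Ifitm3 were lower without passing (-7.04 to -2.95; adjusted p = 0.108). limma called 4 of 12832 genes (Ly6d, Chi3l3, Saa3 and Plac8), with 1693 at an unadjusted p under 0.05 (483 higher, 1210 lower; 315 and 2035 when rescaled without haemoglobin, 678 and 1064 with quantile scaling). Quantile scaling called 13 (6 higher, 7 lower) and rescaling without haemoglobin 6 (4 higher, 2 lower). Camera called 23 of 35 lists. Proliferation genes were lower in PDAC (30 of 30 negative, 12 adjusted over the list alone, adjusted p = 7.54e-10), for example Cdk1, the mitotic kinase gene, at 55.7 and 26.8 against 4.10 RPKM and listed at 0. PDAC primaries 1 and 5 listed 27 and 15 of the 30 genes above 0, so low values in primary 5 are limited by its few detected genes. Also lower were mesenchymal transition (5 over the list alone, 0.00026), MHC class I (0.00155), matrix protease (8 lower and 1 higher over the list alone, 0.00263), fibroblast (2, 0.00263), serine and one-carbon (0.00445), cholesterol synthesis (0.00781), type I interferon (0.00873), hypoxia (0.00972) and basement membrane genes (0.0402). Ductal genes were higher (13 of 15 positive, 5 over the list alone, 5.02e-08), for example Tff2, a mucosal peptide gene, at 0.0817 RPKM and listed at 0 against 27.2 and 1560 RPKM. So were lymphocyte (1 over the list alone, 2.97e-05), pan-leukocyte (0.000117), MHC class II (2, 0.000123), neutrophil (2, 0.000123), erythroid (4, 0.000264), ribosomal (0.000472), glutathione S-transferase (0.00263), epithelial (0.00445), oxidative phosphorylation (0.00463), macrophage (5, 0.0162; median -0.15 and mean 0.56), hepatocyte (0.0195; median 0.00) and lung epithelial genes (1, 0.0404). Camera with an estimated correlation called 0 of the 23 (adjusted p = 0.509 to 0.543), and fry called 0. Leaving out PDAC primary 1 gave 803 genes, leaving out PDAC primary 5 gave 205, leaving out PDAC liver metastasis 5 gave 9, and leaving out a BC library gave 1 to 2. Without the 3 libraries with the fewest genes 72 genes were called (61 higher, 11 lower) and the epithelial list turned its sign (-1.25). The MHC class I (-0.8), ribosomal (0.43), glutathione S-transferase (0.68), hepatocyte (0.46), hypoxia (-1.05), oxidative phosphorylation (0.27), serine and one-carbon (-0.89) and interferon (-0.54) calls were then lost. The calls of 13 lists were lost without PDAC primary 1, among them lymphocyte (0.24), pan-leukocyte (0.31), MHC class II (0.32), macrophage (0.14) and neutrophil genes (1.72). Those of 9 were lost without PDAC primary 5, among them epithelial genes, which turned their sign (-1.26), glutathione S-transferases (0.68) and oxidative phosphorylation genes (0.26). Leaving out a BC library ended the basement membrane call (-1.03 to -0.58 without BC primary 5, lung metastasis 4 or 6), the lung epithelial call (1.66 and 1.67 without lung metastasis 4 or 6), the fibroblast (-0.81) and oxidative phosphorylation (0.41) calls without BC primary 5 and the macrophage call without BC primary 1 (0.61).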

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

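The tests of RNA from the host organ, of the number of detected genes behind the hepatocyte and neutrophil gains, of few detected genes in the PDAC lung metastasis, and, unlike that of single genes, the test of the lists with lung metastases only were chosen only after the result was seen.

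For 11 lists the metastasis effect differed between the models by a test of the difference itself, taken as BC minus PDAC. The median log2 difference over the list was 1.33 for cytosolic ribosomal proteins (35 of 35 members positive), 1.04 for oxidative phosphorylation, 2.95 for pancreatic ductal and progenitor genes (15 of 15 positive) and 2.38 for epithelial genes. It was -2.85 for macrophage and monocyte genes (23 of 24 negative), -3.24 for endothelial genes (13 of 13 negative), -2.62 for hepatocyte genes, -2.31 for immediate early genes, -4.39 for erythroid and platelet genes (10 of 10 negative), -1.98 for proliferation and -1.54 for NF-kB targets. Camera adjusted p ran from 5.34e-09 to 0.0175, and with an estimated correlation the smallest adjusted p was 0.679. The metastases of BC came from the lung, and those of PDAC from the liver in 2 libraries and the lung in 1, so only that library sets model apart from organ. In it the hepatocyte list gained 0.01, against 0.17 and 0.1 in the BC lung metastases, so that difference went with the organ as far as 1 library shows. With lung metastases only, which rests on that 1 PDAC library, camera called 9 of the 11 lists at the preset correlation, among them endothelial (median -5.42) and macrophage genes (-3.28), and the hepatocyte (adjusted p = 0.923) and proliferation calls (0.675) were lost. With an estimated correlation 0 were called (smallest adjusted p = 0.759), and by fry 0. Without PDAC primary 5 the epithelial (0.16), ductal (1.54) and proliferation (-0.87) calls were lost, as were the hepatocyte call without PDAC primary 1 (-1.22), liver metastasis 1 (-1.41) or 5 (-0.94) and the NF-kB call without BC lung metastasis 4 (-1.55) or PDAC liver metastasis 1 (-1.19). The ribosomal (0.14), oxidative phosphorylation (0.15) and ductal calls (0.58) were lost without the 3 libraries with the fewest genes, and the epithelial list turned its sign (-0.32), so none of the 4 lists higher in BC kept its call.

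Hepatocyte and lung epithelial genes were higher in metastases of the organ they belong to. In 5 of 5 metastasis libraries the list of the library's own organ gained more over the primaries of the model than the other organ's list, by which RNA from cells of the host organ is a candidate explanation: the hepatocyte list gained 4.22 and 5.22 in the PDAC liver metastases and 0.01 to 0.17 in the 3 lung libraries, and the lung epithelial list 1.46, 1.55 and 3.45 in these and -0.67 and 0.79 in liver. Fewer detected genes in the metastases were excluded as a cause of the hepatocyte gain, since the smallest gain in liver lay 4.05 above the largest in lung although the lung libraries include those with the fewest genes. A sort on GFP or YFP is meant to remove unlabelled host cells, though genes of red blood cells were abundant in the sorted PDAC metastases. None of the genes of either list is held by another list. Abundant ones in liver included Apoa2 at 424 and 517 RPKM and Alb at 30.8 and 381 RPKM. Sftpc was at 34200 RPKM in the PDAC lung metastasis and at 20.6 and 0.905 RPKM in BC lung metastases 4 and 6. That labelled tumour cells take up the expression of their organ is the biological explanation that the design names, and it was not tested. It would give the same 5 of 5, so that count cannot tell it from RNA of host cells.

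Of 17 neutrophil genes 17 had higher means in the BC lung metastases than in the BC primaries, and 5 were higher in both metastases than in both primaries, with S100a8 at 1500 and 939 against 15.0 and 13.2 RPKM. A lower number of detected genes stays open as a cause, with 1 library on each side. Within BC the neutrophil list gained 3.61 in metastasis 4, which lists 18665 genes, and 1.16 in metastasis 6, which lists 10938. The gain was thus 2.45 higher in the library with more genes. Primaries 1 and 5 list 18685 and 20478 genes, so metastasis 4 listed nearly as many as primary 1, though its gain rests on 1 library. RNA from neutrophils in the sorted samples may account for the rise and stays open: of the 10 neutrophil genes most abundant in PDAC liver metastasis 5, 5 were higher in both BC metastases (S100a8, S100a9, Retnlg, Ngp and Lcn2) and 5 were not (Camp, Ltf, Il1r2, Elane and Mmp8), with Camp at 50.9 and 0.926 RPKM in metastases 4 and 6 against 0.853 and 1.61 RPKM. The 5 that were not were each higher in metastasis 4 than in both primaries and failed only through metastasis 6. Mmp8, for example, was at 11.4 and 0.148 RPKM in metastases 4 and 6 against 0.151 and 0.128 RPKM. In metastasis 6, 15.9% of genes with a mean above 20 RPKM in the other libraries lay under 0.5 RPKM, against 3.96% in metastasis 4. The count of 5 is limited by this. A GFP sort is meant to remove neutrophils, but haemoglobin genes of red blood cells were still found. They took 0.0235 and 0.107% of the summed RPKM in BC metastases 4 and 6, against 0.00607 and 0.0084% in primaries 1 and 5. The sort therefore does not settle the question. No gene of the list is held by another list. Expression of these genes by the tumour cells in the lung is the biological explanation, and it was not tested.

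Of the genes called lower in the PDAC lung metastasis, 53, most were near 0 in that library and abundant elsewhere. Under 0.5 RPKM there were 47 of the 53, which their choice as genes called lower largely fixes. Of all 3229 tested genes with a mean above 20 RPKM in the other 8 libraries, called or not, 611 (18.92%) were under 0.5 RPKM in this library, by which few genes detected in it is a candidate explanation. The same share was 0.94% to 22.87% in the other 8 libraries, with a median of 5.35% and the highest in PDAC primary 5. A drop shared with the other PDAC metastases had been set as a median log2 difference under -1 in the liver metastases. That limit was not reached: the median of the 53 genes there was -0.59 (quartiles -0.97 to -0.36), against 0.08 over all genes. Most of the 53 were thus lower in liver too, by less than the limit. Both comparisons use the same primaries, so a smaller shared drop is neither shown nor excluded. A change of these genes in the lung, such as that of Cyc1 from 265 and 110 to 0.131 RPKM, rests on 1 library and was not tested apart from it.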

How the results depend on the processing

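The alternatives chosen after seeing the data were the rescaling without haemoglobin genes, the fit without the 3 libraries with the fewest genes, the crossed replicate block and the list tests with lung metastases only. Under the alternatives other than leaving out 1 library, list results kept direction and call in 545 comparisons with the reported fit, lost the call in 246 and turned in 8, and values of named genes did so in 3901, 86 and 13, with 115 newly past the threshold. With each library left out in turn, the list results kept direction and call in 737, lost the call in 88 and turned in 13, and the gene values in 2897, 101 and 17, with 144 newly past the threshold. Gene values counted as turned include some that went to 0, such as Fabp1 in the primaries without PDAC primary 5. Where leaving out a library leaves an arm with 1 library, as in the PDAC lung comparison throughout, the lone library is assumed to vary like the other groups. The hepatocyte, macrophage, erythroid, neutrophil and proliferation calls of PDAC liver held without each library in turn at the preset correlation and were lost with an estimated one (adjusted p = 0.153 to 0.617). Apart from hepatocyte genes their size depended on the primary, from a median of 1.24 against primary 1 and 2.95 against primary 5 for proliferation to 2.55 and 8.94 for erythroid genes. The count-based tests planned for a table of counts were not run because the values are not counts, and the PDAC lung comparisons cannot be made without the lung library. Low values are limited in what they show, since between 0.94% and 22.87% of the genes with a mean above 20 RPKM in the other libraries lay under 0.5 RPKM in a library. This share did not follow depth alone: it was 22.87% in PDAC primary 5 with 40200000 reads on genes and 4.75% in PDAC liver metastasis 1 with 28100000. Where no cause is named below, the cause was not tested.

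With a pseudocount of 0.1, PDAC liver gave 0 genes, PDAC lung 270 (7 higher, 263 lower), the comparison over both models 0 and liver against lung 188 (185 higher, 3 lower). With a pseudocount of 5 these were 2 for PDAC liver, 117 for PDAC lung (108 higher, 9 lower) and 93 for liver against lung (16 higher, 77 lower). Without a filter on low values PDAC liver gave 0, PDAC lung 251 (205 higher, 46 lower), both models 0, liver against lung 230 (50 higher, 180 lower) and the primaries 0. With a mean of at least 5 PDAC liver gave 0, both models 2 and liver against lung 20, and 6 lists were called in BC. Quantile normalization gave 0 in PDAC liver, 161 in PDAC lung (121 higher, 40 lower), 6 over both models, 91 for liver against lung (16 higher, 75 lower) and 13 for the primaries (6 higher, 7 lower). Without the trend and robust steps PDAC liver gave 2, PDAC lung 0, both models 0 and the primaries 1. Library weights gave 2 in BC, 338 in PDAC lung (117 higher, 221 lower), 2 over both models, 557 for liver against lung (422 higher, 135 lower) and 65 for the primaries (35 higher, 30 lower), in a weighting that did not converge in all fits. With only the libraries of that model in the fit BC gave 73 (34 higher, 39 lower), PDAC liver 0, PDAC lung 1 and liver against lung 2. With the models weighted equally the comparison over both gave 0. Rescaling without haemoglobin gave 0 in PDAC liver and 0 over both models, and ended the list calls of glutathione synthesis in BC and PDAC liver, of oxidative phosphorylation over both models and in the primaries, and of basement membrane in the primaries. It moved the median log2 difference of all genes from -0.29 to -0.64 in BC, from 0.08 to -0.14 in PDAC liver, from -0.16 to -0.45 over both models, from -0.24 to -0.42 in the difference between models, from 0.53 to 0.33 for liver against lung and from -0.31 to -0.76 for the primaries. Quantile normalization moved these medians to 0.07, -0.13, -0.02, 0.06, -0.08 and 0.05, and that of PDAC lung from -0.5 to -0.05. The rescaling without haemoglobin also sets all libraries to a common sum. In BC, haemoglobin took at most 0.107% of the summed RPKM, so the shift there came from the unequal sums and not from haemoglobin. These sums were 377154 and 288171 in BC primaries 1 and 5 and 390847 and 546533 in BC lung metastases 4 and 6. TMM scaling changed no call of a list and no count of genes.

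With the replicate number as a block, limma called 0 genes in PDAC liver, 0 in PDAC lung and 0 for liver against lung. With mouse as a random replicate block over both models 6 genes were called, all higher, and with the crossed replicate block PDAC liver gave 46, all higher. Among the lists called without it, the block ended the ribosomal and fibroblast calls in PDAC liver, the NF-kB and lymphocyte calls in PDAC lung and the glycolysis call of liver against lung, and no other.

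With an estimated correlation camera called 0 lists in each of the 7 comparisons. By fry 1 list was called in PDAC liver and 1 for liver against lung, the hepatocyte genes in both, and 0 in the other 5.

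Without the 3 libraries with the fewest genes (BC lung metastasis 6, PDAC primary 5 and the PDAC lung metastasis) PDAC liver gave 0 genes, both models 0 and the primaries 72 (61 higher, 11 lower), and 22 lists were called for the difference between models (6 higher, 16 lower). In PDAC liver the lists of epithelial (0.59), lymphocyte (-1.17) and basement membrane genes (0.19) turned, with Itga2 (0.1), Rac2 (-0.22), Coro1a (-0.34), Tff2 (0.16) and Sirt6 (-0.34). Over both models the lists of epithelial (0.42), lymphocyte (-0.19) and ductal genes (0.06) turned, with Tff2 (0.05). In the difference between models epithelial genes (-0.32), Cldn5 (0.6), Tff2 (-0.22), Trp53 (1.18) and Sirt6 (0.1) turned. In the primaries epithelial genes (-1.25) turned and Fabp1 went to 0. With lung metastases only, the difference between models turned for Apoc3 (0.04) and Trp53 (0.16), and camera called 9 lists, without hepatocyte (0.09) and proliferation genes (-0.24). List calls were also lost without the 3 libraries with the fewest genes in BC (4), PDAC liver (3), over both models (4), in the difference between models (3) and in the primaries (8).

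Leaving out each library in turn gave 0 to 1032 genes in PDAC liver, 0 to 1547 in PDAC lung, 0 to 10 over both models, 0 to 104 for the difference between models, 0 to 329 for liver against lung and 1 to 803 for the primaries. The lists called ran from 6 to 15 in BC, 11 to 17 in PDAC liver, 7 to 15 in PDAC lung, 10 to 20 over both models, 5 to 10 for liver against lung and 10 to 24 for the primaries. In PDAC liver the values without 1 library ran from -4.9 to 0.58 for epithelial genes, -5.01 to -0.02 for ductal genes, -1.18 to 4.18 for lymphocyte genes, -0.01 to 3.83 for pan-leukocyte genes, -2.53 to 0.19 for basement membrane genes and -1.24 to 0.26 for ribosomal proteins. Single genes there ran from -3.87 to 0.1 for Itga2, -0.22 to 8.58 for Rac2, -0.34 to 9.04 for Coro1a, -5.63 to 0.16 for Tff2, -1.66 to 1.29 for Trp53 and -0.34 to 1.83 for Sirt6. In PDAC lung the ranges were -0.54 to 4.9 for lymphocyte genes, -2.06 to 0 for Gstt1 and -2.17 to 0 for Sirt6. Over both models they were -2.33 to 0.01 for epithelial genes, -0.14 to 2.18 for lymphocyte genes, -2.1 to -0.02 for ductal genes and -1.2 to 0 for Sirt6. For the difference between models they were 0.16 to 5.59 for epithelial genes, -0.06 to 2.68 for Gstt1 and -2.23 to 0.72 for Trp53. In the primaries they were -2.44 to 0.37 for basement membrane genes, -1.26 to 4.27 for epithelial genes, 0 to 7.78 for Fabp1, -0.01 to 8.84 for Sftpd, -0.84 to 7.59 for Napsa and -0.38 to 10.21 for Cd79a. For most of these 1 end of the range was reached without PDAC primary 1 and the other without PDAC primary 5.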

Other observations

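The tests of the 65 genes and of the splits in this part were written before the result was seen, except the counts over the 36 splits and the smallest adjusted p per split, and genes outside the rule for named genes were chosen after their values were seen.

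Genes of the glutathione and NRF2 systems, which remove reactive and toxic compounds, went different ways within their families. Of 21 measured glutathione S-transferases 15 had higher values in PDAC than in BC primaries and 6 lower. Gstm1 was at 10.7 and 5.25 RPKM in BC primaries and 16.4 and 115 RPKM in BC lung metastases, and at 52.7 and 114 RPKM in PDAC primaries, 284 and 101 RPKM in PDAC liver metastases and 99.7 RPKM in the PDAC lung metastasis. Gsta4 was at 107 and 2320 RPKM in PDAC primaries 1 and 5 and at 0.164 RPKM in the PDAC lung metastasis, and passed there adjusted over the list alone (adjusted p = 0.0228, 0.0764 over all genes by limma). Gsto1 was at 3060 RPKM in PDAC primary 5 and at 45.1 to 423 RPKM in the other libraries, and Gstt2 was at 43.5 RPKM in PDAC primary 1, listed at 0 in PDAC primary 5 and at 61.4 RPKM in the PDAC lung metastasis. Among NRF2 targets, the ferritin chain genes Fth1 (log2 1.17 ± 0.31, SE, n = 5 against 4) and Ftl1 (1.12 ± 0.32) and the pentose phosphate enzyme gene Taldo1 (1.29 ± 0.40) were higher in metastases over both models when adjusted over the list alone (0.0379, 0.0379 and 0.0464), and did not pass over all genes (limma adjusted p = 0.853). Camera did not call that list there (adjusted p = 0.087). The chemokine gene Ccl5 (3.74 ± 0.89) likewise passed over its list alone, at 0.024, and not over all genes (0.61).

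Of 20 acinar genes in the table, which make digestive enzymes, 4 passed the filter. Reg1, which did not, was at 455 RPKM in PDAC primary 5 and listed at 0 in PDAC primary 1 and both liver metastases. Clps, which did, was at 126 RPKM in the PDAC lung metastasis and 5.95 RPKM in PDAC primary 1. The mean log2(RPKM + 1) over the 20 genes was 1.67 in PDAC primary 5 and 0.23 to 0.78 elsewhere. Hmga2, a chromatin protein gene of embryonic tissue among 3 tested oncofetal genes, was at 6.61 to 11.4 RPKM in the 4 BC libraries and 14.7 RPKM in PDAC primary 5, and at 0.0753 to 0.308 RPKM in the other 4 PDAC libraries. The imprinted transcript H19 was at 85.9 RPKM in BC primary 5 and at 6.50 RPKM in BC primary 1. The 9 adipocyte and muscle genes in the table, 3 of which passed the filter, had a mean log2(RPKM + 1) of 0.15 to 0.84 per library. These 3 lists were too small for a test. TGF-beta target, Wnt target, p53 target, unfolded protein response, fatty acid and mammary keratin genes were called by camera in none of the 7 comparisons, and over both models fatty acid (0.795), unfolded protein response (0.842), mammary keratin (0.49), cholesterol (0.631) and serine and one-carbon genes (0.849) did not pass.

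Oxidative phosphorylation and ribosomal protein genes, 65 in all, gained 1.02 over the other genes in the BC lung metastases together, 0.23 in metastasis 4 alone and 1.81 in metastasis 6 alone, which lists 10938 genes. Their median log2 difference of 0.7 lay at percentile 63.88 of 10000 random lists matched on gene length and mean expression, whose median was 0.68. In the alternatives the gain of the oxidative phosphorylation list over the other genes ranged from 0.4 to 1.75.

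For the comparison over both models, libraries were also split in every other way within the models, 60 splits with the real one. For the 1 gene called, only the real split gave as many and the highest other gave 0, which passed the limit set in advance. The margin was narrow: the smallest limma adjusted p was 0.0371 in the real split and 0.0649 in another. A count of 1 against 0 therefore does not firmly exclude chance. The call itself was lost with a pseudocount of 0.1, without a filter, without the trend and robust steps, with the models weighted equally, when rescaled without haemoglobin, without the 3 libraries with the fewest genes and without each of 6 single libraries. Chance cannot be excluded for the 16 lists called, since the highest other split gave 18 and 5 splits gave as many. Nor can it be excluded for the 474 genes separated the same way in both models, since 13 splits gave as many. The highest other split gave 1098, more than the real one, which points to a structure among the libraries other than primary against metastasis. These splits treat the PDAC libraries as exchangeable, although their numbers were taken to pair them by mouse. Of the 36 splits that, like the real one, put 1 library of each PDAC number with the primaries, 1 gave as many genes (the real one), 5 as many lists and 10 as many separated genes. The other 24 left a PDAC number all on 1 side, and 0, 0 and 3 of them gave as many. The split with 1098 set PDAC primary 5, PDAC liver metastasis 1 and the PDAC lung metastasis, which list 10410, 12144 and 9530 genes, against PDAC primary 1 and liver metastasis 5, which list 15907 and 18717.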
